A study of Arabidopsis thaliana with 6 samples.

How the data were processed

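Leaf RNA of Arabidopsis thaliana plants 25 days old was sequenced as messenger RNA libraries on an Illumina HiSeq instrument. The 6 libraries form 2 groups of 3, wild type and the pub2pub4 double mutant, both labelled mock. What the mock treatment was is not given in the sources used here. The labels do not say whether replicates came from separate plants or pools, so p-values measure the spread between these samples, which may be technical.

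The table deposited by the authors holds expected counts, that is, estimated reads per gene that need not be whole, for 33602 genes. Of its values, 95.1% were whole numbers. Per the submitters' processing notes, TopHat2 2.1.0, RSEM 2.1.30 and the TAIR10 genome were used, with the role of each tool not stated. The strand setting, the gene annotation release and any filter are not given in the sources used here. The deposited table also gives a length per gene, used only in a check for length bias. Totals were 20506882 to 20732799 expected counts per library. At this depth 9807 genes had no count in any library.

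Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group (minimum count 10, minimum total count 15), TMM scaling, a robust quasi-likelihood fit with group as the only term, and Benjamini-Hochberg adjustment over the 19019 genes kept. A gene is called changed, risen or fallen at an adjusted p under 0.05. Adjusted p-values for genes come from this fit, which is two-sided. Standard errors of log2 fold changes, written ± with SE, were derived from the fold change and the F statistic. Levels are TMM-scaled CPM (counts scaled by library size) as mean ± SD over 3 libraries. On simulated counts with the means and spread of these libraries, over 18882 genes, the test recovered 52% of genes changed 1.5-fold, 86% of those changed 2-fold and 94% of those changed 3-fold, with 17 false calls. True calls at 1.5-, 2-, 3- and 4-fold numbered 26, 43, 47 and 47, so the share of false calls was above the threshold of 0.05. With no simulated change it made 10 calls. Genes were drawn independently, with no shift shared by the genes of a library. The simulation therefore does not give the rate of false calls where such shifts occur.

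Before the data were examined, 27 gene lists were fixed (21 pathways or families and 6 sets of cell type markers), besides the 2 targeted genes. The 25 lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, fry for one direction and fry for either direction (mixed), and the counts of members called over all genes and adjusted over the list alone. On simulated data with 21 lists of random genes drawn independently, the list test called the 1 shifted list and 0 of the unshifted lists. The real lists had estimated correlations between members of up to 0.762. The simulation therefore does not give the rate of false calls for lists whose members move together. Shares of library composition were compared by exact two-sided permutation tests, which with 3 against 3 cannot give a p under 0.1.

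The rule for named genes was also fixed before the data were examined. It takes PUB2 and PUB4; then the 8 largest rises and the 8 largest falls among called genes with a symbol, with no overlap between the 2 groups of libraries and with a mean of at least 16.6 CPM, the median of the tested genes; then up to 4 members per list with the smallest unadjusted p. Any other gene named was chosen after its values were seen. Symbols are those of the table or of a synonym in the reference gene table, in which 32835 of the table's identifiers had a row.

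Chromosome positions come from the TAIR10.1 annotation, not from the deposited table, which has none. Of 128 genes looked up because they were named or singled out, 32 have a span in that annotation that overlaps another gene, and for 21 of them the partner was at 1 CPM or more in wild type. Since the strand setting is not stated, reads of such pairs cannot be told apart with certainty. Examples with a partner at a higher level in wild type are COR15B (4.50 against 50.7 CPM), SLAC1 (4.52 against 43.1 CPM) and GL2 (18.0 against 290 CPM). Close paralogs, such as KIN1 and KIN2, COR15A and COR15B, the clustered CRK genes and the copies in the chloroplast inverted repeat, may share reads, and their values are uncertain to that extent.

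Alternatives were the replicate number as a block, each library left out, DESeq2 1.42.0, limma-voom, median-of-ratios factors, library totals alone, no filter and a stricter filter (at least 5 CPM in 3 libraries), organelle-encoded genes or the 10 highest genes left out, no rounding, and a test against 1.5-fold. Replicate numbers were not taken as pairs. Families named by their product in the reference annotation were tested for an excess of called genes with one-sided Fisher exact tests over the tested genes, for 689 families with at least 5 tested members. Risen and fallen genes were tested apart, each with its own Benjamini-Hochberg adjustment over the families. In 5 simulated draws of random gene sets this test called 1 family in all, and it called the planted family in 5 of 5.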

Results

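The data describe leaf transcript levels of the pub2pub4 double mutant and wild-type Arabidopsis under mock conditions, with 3 libraries per genotype. PUB2 and PUB4 encode U-box proteins with ARM repeats, a class of E3 ubiquitin ligases, and the series title places both in plant immunity. The comparison asks how leaf transcript levels differ without the 2 genes when no immune elicitor is named in the labels. Library totals ran from 20506882 to 20595904 expected counts in wild type and from 20572341 to 20732799 in the mutant. Of 33602 genes in the table, 19019 had enough counts to be tested.

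Transcripts of both targeted genes were low in the mutant. PUB2 (AT5G67340, chromosome 5, 26864395 to 26867847, plus strand, TAIR10.1) was at 9.05 ± 1.44 CPM (SD, n = 3) in wild type and 0.504 ± 0.108 CPM (SD, n = 3) in pub2pub4. Its log2 fold change was -4.15 ± 0.22 (SE), with an adjusted p of 1.84e-04. PUB4 (AT2G23140, chromosome 2, 9845410 to 9849379, minus strand, TAIR10.1) went from 21.03 ± 2.36 to 3.22 ± 0.746 CPM (SD, n = 3 each), a log2 fold change of -2.71 ± 0.17 (SE) and an adjusted p of 5.19e-04. No mutant library overlapped a wild-type library for either gene. Both calls held without each of the 6 libraries in turn. The counts are per gene, so they do not show which part of each transcript remained.

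**Figure D1:**
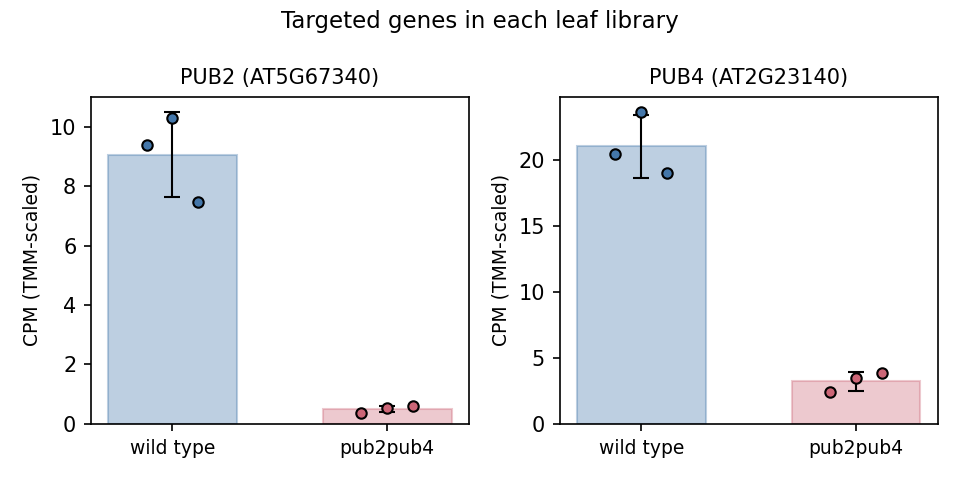
TMM-scaled CPM of PUB2 and PUB4 (y axes, linear, from 0) in wild type and pub2pub4 leaves (x axis); bars are means, error bars are SD over 3 libraries and points are libraries. PUB2 fell from 9.05 to 0.504 CPM and PUB4 from 21.03 to 3.22 CPM.

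In pub2pub4 leaves 9 of 19 tested abscisic acid and cold response genes rose, and 10 of 19 cysteine-rich receptor-like kinase genes fell. Camera called both lists (adjusted p 1.89e-16 and 3.55e-16), and with an estimated correlation the adjusted p was 0.279 for each. In all, 848 of the 19019 tested genes changed, of which 474 were higher and 374 lower in the mutant. A log2 fold change of at least 1 in size was seen for 120 of the higher and 134 of the lower genes. All 848 had no overlap between the 2 groups of libraries, as had 26.2% of all tested genes, where chance order gives 10%. Libraries of a group stood apart from each other. On the first principal component (45.2% of variance) wild type 3 was at -17.7, against -31.4 and -37.0 for the other wild-type libraries. On the second (24.4%) pub2pub4 1 and pub2pub4 3 were at 31.8 and -38.8. Some changed genes also varied within wild type. Wild type 3 lay nearer the mutant for KIN2 (107 CPM, against 61.2 and 64.1 in wild type 1 and 2) and SOBIR1 (160, against 236 and 251). For COR15B (4.94, against 5.11 and 3.45) and CRK5 (25.2, against 26.5 and 25.9) wild type 3 stood less apart. DESeq2 called 1452 genes, and 26 passed a test against 1.5-fold. With the replicate number as a block 1066 genes were called, 45.9% of them higher, against 55.9% of the 848. The number of calls depended on single libraries: it was 132 without wild type 1, 86 without wild type 2, 540 without pub2pub4 1 and 91 without pub2pub4 2, while without pub2pub4 3 the genes called higher numbered 756. All 848 genes kept their direction without each library in turn, which follows from the lack of overlap between the groups. Of them 54, 30 higher and 24 lower, were called each time.

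Under the naming rule the largest rises included several genes known to respond to drought, cold or abscisic acid. PUB19 (AT1G60190), another U-box ubiquitin ligase gene, rose from 8.45 ± 3.70 to 73.5 ± 33.3 CPM (SD, n = 3 each), a log2 change of 3.12 ± 0.53 (SE, adjusted p 0.0464). COR15B (AT2G42530), a cold-regulated gene, rose by 2.77 ± 0.20 (SE, adjusted p 0.00274), and P5CS1 (AT2G39800), for proline synthesis, by 1.74 ± 0.18 (SE, adjusted p 0.0105). ATHB-7, a homeodomain-leucine zipper transcription factor gene, BGLU11, a beta-glucosidase gene, and PXG3, a caleosin gene, rose by 2.11, 2.04 and 2.03 on the log2 scale. RD29A and KIN2, both dehydration- and cold-responsive, rose by 2.04 and 1.67. Of these 8 genes, COR15B and P5CS1 were called without each library in turn. RD29A was called in 4 of the 6 such fits, PUB19 and KIN2 in 2, and ATHB-7, BGLU11 and PXG3 in 1.

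The largest fall under the rule was that of PI4KG3 (AT5G24240), annotated as a phosphatidylinositol 4-kinase gamma-like gene, from 47.3 ± 3.11 to 0.391 ± 0.179 CPM (SD, n = 3 each; log2 -6.90 ± 0.18 SE, adjusted p 1.62e-06). It was called without each library in turn. CRK6 (-2.58), CRK4 (-2.42) and CRRSP38 (-1.66) belong to or are related to the cysteine-rich receptor-like kinases. PUB23, a U-box ligase gene of immune signalling, changed by -1.49, HIR3 by -1.47 and XBAT34 by -1.44. The chloroplast ribosomal RNA gene RRN23S.1 changed by -1.43, and its value is uncertain because a second copy in the inverted repeat shares its sequence. With a library left out, CRRSP38 was called in 5 of the 6 fits, RRN23S.1 in 3, CRK6, CRK4, PUB23 and HIR3 in 2 and XBAT34 in 1.

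Abscisic acid and cold response genes were higher as a group (camera adjusted p 1.89e-16), although the adjusted p was 0.279 with an estimated correlation. Of 19 tested members, 9 rose, 0 fell and 10 did not pass the test, and the median log2 change was 1.48. Adjusted over the list alone, 17 members were higher. COR47, a dehydrin gene, went from 131 ± 25.3 to 321 ± 10.1 CPM (SD, n = 3 each; log2 1.29 ± 0.13 SE, adjusted p 0.00714), and RD29A from 47.9 ± 12.5 to 197 ± 41.3 CPM (adjusted p 0.0166). The call of COR47 held without each library in turn, and that of RD29A held in 4 of the 6 fits. The protein phosphatase genes ABI2 and HAB1, negative regulators of abscisic acid signalling and named after their values were seen, rose by 1.23 and 1.05. Fry, which asks whether members move one way, gave the list an adjusted p of 0.0181.

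Cysteine-rich receptor-like kinases, a family of cell-surface kinases with extracellular cysteine motifs, were lower as a group (camera adjusted p 3.55e-16), although the adjusted p was 0.279 with an estimated correlation. Of 19 tested members, 10 fell, 0 rose and 9 did not pass the test, with a median log2 change of -1.25. All 19 fold changes were negative, and 17 members were lower when adjusted over the list alone. CRK5 (AT4G23130) fell from 25.9 ± 0.672 to 7.02 ± 0.957 CPM (SD, n = 3 each; log2 -1.88 ± 0.11 SE, adjusted p 2.47e-04) and CRK19 from 57.6 ± 3.90 to 35.6 ± 2.54 CPM (adjusted p 0.00870). These 2 calls held without each library in turn. CRK13 changed by -1.26, and CRK23, at 1.07 CPM in wild type, by -2.82, both called in 3 of those 6 fits. By fry the adjusted p of the list was 0.0181.

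**Figure D2:**
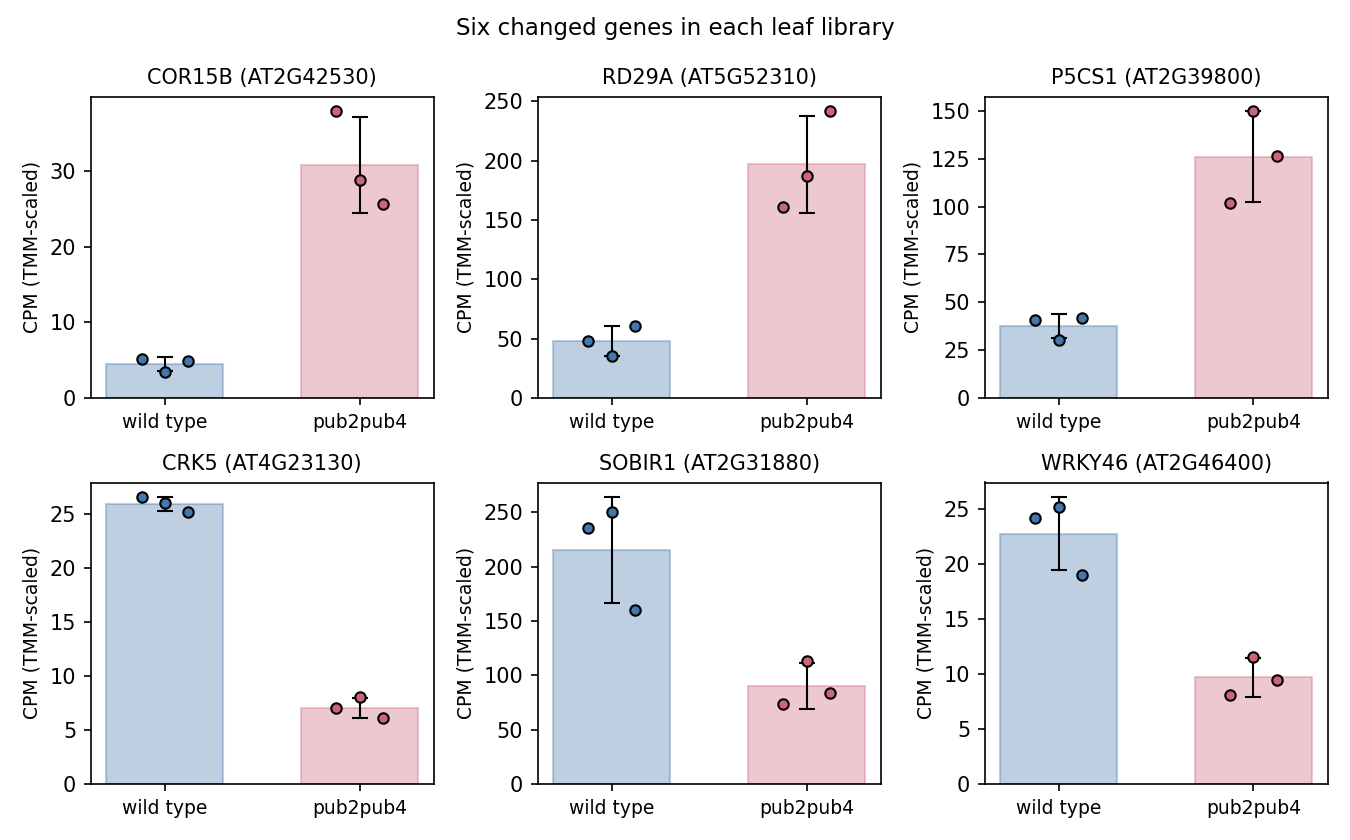
TMM-scaled CPM (y axes, linear, from 0) of COR15B, RD29A, P5CS1, CRK5, SOBIR1 and WRKY46 in wild type and pub2pub4 leaves (x axis); bars are means, error bars are SD and points are the 3 libraries per group. The first 3 genes were higher in every mutant library than in any wild-type library and the last 3 lower.

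Among receptors and early signalling components of pattern-triggered immunity (PTI), 4 of 34 tested genes fell, 0 rose and 30 did not pass the test. The median log2 change was -0.21, and 12 members were lower and 1 higher when adjusted over the list alone. SOBIR1, an adaptor kinase of receptor-like proteins, fell from 215 ± 48.8 to 90.0 ± 20.9 CPM (SD, n = 3 each; log2 -1.26 ± 0.23 SE, adjusted p 0.0435). BIK1, a cytoplasmic kinase downstream of immune receptors, changed by -0.53, BIR1, a receptor-like kinase that restrains immunity, by -0.51 and MPK11, a MAP kinase, by -1.71. Each of these 4 calls was lost in at least 3 of the 6 fits with a library left out. Camera gave an adjusted p of 3.37e-07, the adjusted p was 0.355 with an estimated correlation, and fry gave 0.105.

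Of 9 immune U-box ubiquitin ligase genes tested, PUB22 (-1.17 ± 0.18 SE, adjusted p 0.0174) and PUB23 (-1.49 ± 0.24 SE, adjusted p 0.0289), which are known to dampen immune signalling, fell and 7 did not pass the test. All 9 had negative fold changes, PUB25 and PUB26 among them with -0.52 and -0.39, and the same 2 genes were lower when adjusted over the list alone. The adjusted p of the list was 3.29e-04 by camera, the adjusted p was 0.279 with an estimated correlation, and fry gave 0.0439. PUB22 and PUB23 were called in 3 and 2 of the 6 fits with a library left out.

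Of 18 intracellular immune receptor (NLR) genes, CHS1 and SOC3 fell and 16 did not pass the test, and 6 were lower when adjusted over the list alone. CHS1 changed by -0.87 ± 0.12 and SOC3 by -0.65 ± 0.14 (SE, adjusted p 0.0123 and 0.0386). These neighbours overlap on opposite strands over 3193 bases, so their reads may be shared. LAZ5 and CHS3 had log2 changes of -0.47 and -0.32, with adjusted p 0.0833 and 0.0834. All 18 fold changes were negative, with a median of -0.23. Camera gave an adjusted p of 2.97e-06, the adjusted p was 0.279 with an estimated correlation, and fry gave 0.0622. CHS1 was called in 4 and SOC3 in 1 of the 6 fits with a library left out.

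Salicylic acid and systemic resistance genes were lower as a group by camera (adjusted p 3.55e-10), while the adjusted p was 0.364 with an estimated correlation and 0.172 by fry. WRKY46 (-1.23 ± 0.16 SE, adjusted p 0.0123) and WRKY62 (-3.03 ± 0.57 SE, adjusted p 0.0357), both transcription factor genes, fell, while 34 of the 36 members did not pass. The median log2 change was -0.83, and 33 of 36 fold changes were negative. The count adjusted over the list alone was 14 lower and 1 higher. GRXC9 and AED1 had log2 changes of -1.07 and -2.08 (adjusted p 0.0647 and 0.0686). The marker PR1, named after its values were seen, was at 25.4 ± 15.2 CPM in wild type and 2.51 ± 1.88 CPM in the mutant (SD, n = 3 each), with an adjusted p of 0.104. WRKY46 was called in 4 and WRKY62 in 1 of the 6 fits with a library left out.

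Of 17 genes used as markers of PTI induction, 0 were called by edgeR, with 5 lower at an unadjusted p under 0.05. DESeq2 called 5 lower and limma-voom 0. WRKY22, MYB51, WRKY53 and NHL10 had log2 changes of -0.84, -0.98, -1.31 and -1.99, with adjusted p of 0.0855, 0.123, 0.166 and 0.188. Of the 17 fold changes 12 were negative and 5 positive, the largest that of CYP82C2, named after its values were seen, at 3.85 ± 1.80 (SE, adjusted p 0.331). The list's median was -0.56 and its camera adjusted p 0.00138. That call was lost without pub2pub4 3 (0.147), the adjusted p was 0.364 with an estimated correlation, and fry gave 0.197. No member was called when adjusted over the list alone.

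Genes of aliphatic glucosinolate synthesis, which makes methionine-derived defence compounds, were higher as a group by camera (adjusted p 3.75e-12), while the adjusted p was 0.279 with an estimated correlation and 0.0439 by fry. Of 16 tested, 8 rose, 0 fell and 8 did not pass the test, with a median log2 change of 0.61, and 15 were higher when adjusted over the list alone. MYB29, a transcriptional activator of the pathway, rose by 0.60 ± 0.09 (SE, adjusted p 0.0159), and CYP79F1, for the entry step, went from 203 ± 8.42 to 334 ± 64.1 CPM (SD, n = 3 each; adjusted p 0.0297). SOT18 and FMOGS-OX1 rose by 0.65 and 0.63. These 4 calls were each lost in at least 3 of the 6 fits with a library left out.

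Anthocyanin and flavonoid synthesis genes were also higher by camera (adjusted p 1.29e-08), while the adjusted p was 0.279 with an estimated correlation and 0.0439 by fry. Of 13 tested, CHS, CHI, F3H and MYB75 rose and 9 did not pass the test, while all 13 fold changes were positive with a median of 0.89. CHS, the first enzyme of the pathway, rose from 33.1 ± 6.58 to 58.1 ± 4.70 CPM (SD, n = 3 each; log2 0.81 ± 0.14 SE, adjusted p 0.0252). CHI, F3H and the activator MYB75 rose by 0.67, 0.89 and 1.23. Adjusted over the list alone, 6 members were higher. Each of the 4 genes lost the call in at least 3 of the 6 fits with a library left out.

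In the jasmonate list 2 of 24 genes rose and 22 did not pass the test. They were LOX2, a lipoxygenase of jasmonate synthesis (2839 ± 270 to 4344 ± 673 CPM, SD, n = 3 each, adjusted p 0.0343), and JAZ3, a repressor of the response (log2 0.46 ± 0.08 SE, adjusted p 0.0270). The same 2 were higher when adjusted over the list alone. CORI3 and AOC2 had log2 changes of 1.71 and 0.45 (adjusted p 0.0966 and 0.110). The list's median was 0.10 and its camera adjusted p 0.0114. The call was lost without wild type 1 (0.945) and without pub2pub4 3 (0.0542), the adjusted p was 0.564 with an estimated correlation, and fry gave 0.354. JAZ3 was called in 3 and LOX2 in 1 of the 6 fits with a library left out.

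**Figure D3:**
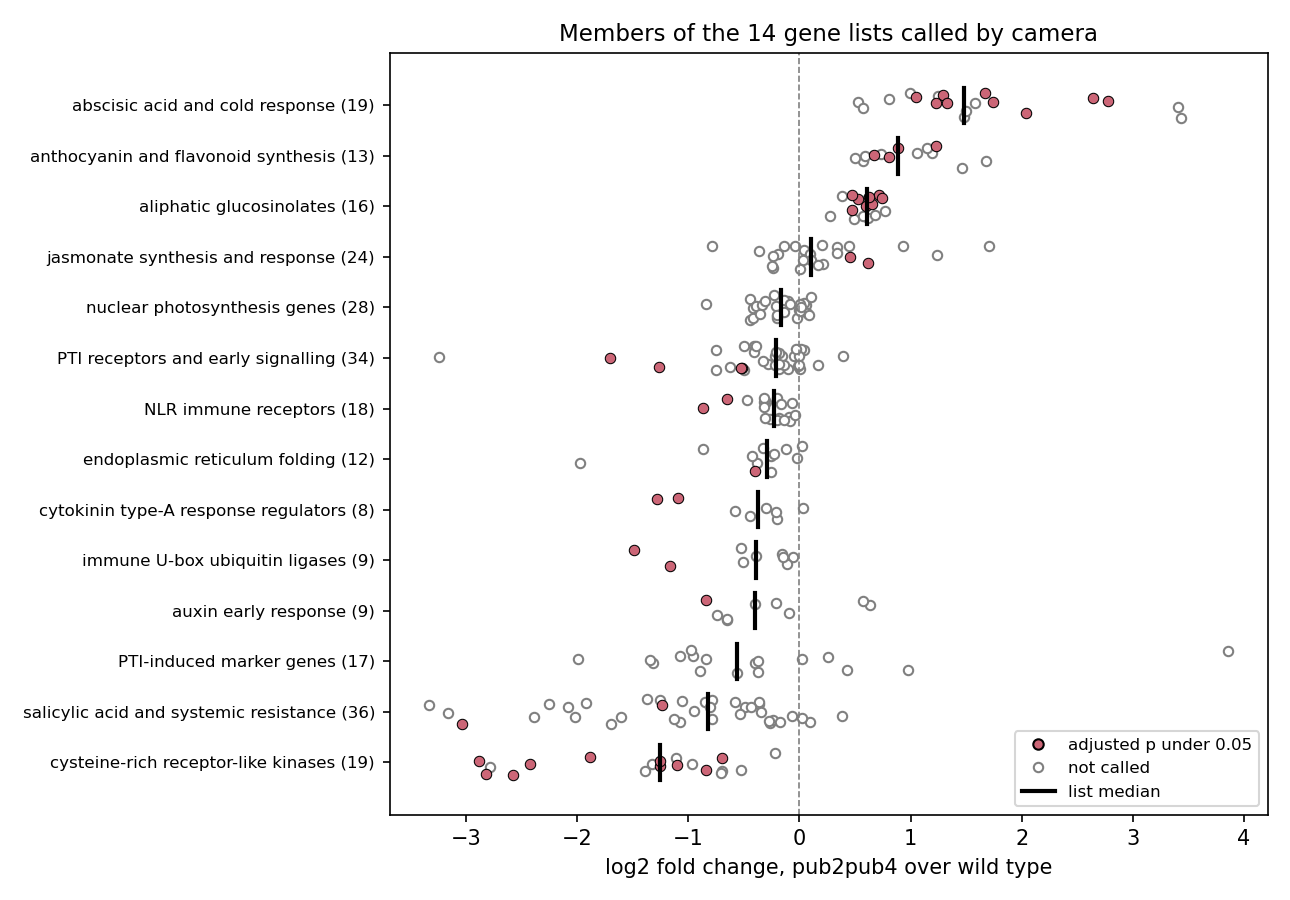
Log2 fold change of pub2pub4 over wild type (x axis) for each tested member of the 14 lists called by camera (y axis, number of tested members in brackets); filled points passed an adjusted p under 0.05, open points did not, and bars are list medians. Medians ran from -1.25 for the cysteine-rich receptor-like kinases to 1.48 for abscisic acid and cold response genes.

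Cytokinin type-A response regulators, auxin early response genes and endoplasmic reticulum folding genes were lower by camera, with adjusted p of 7.11e-04, 0.0319 and 2.23e-05. With an estimated correlation the adjusted p was 0.429, 0.279 and 0.279 in that order, and by fry 0.172, 0.0439 and 0.0439. ARR15 (-1.28 ± 0.27 SE, adjusted p 0.0371) and ARR5 (-1.09 ± 0.22 SE, adjusted p 0.0465), which are induced by cytokinin, fell among 8 type-A regulators, and ARR9 and ARR6 had log2 changes of -0.44 and -0.58. IAA19, an auxin-induced repressor gene, fell among 9 auxin genes (-0.84 ± 0.18 SE, adjusted p 0.0380), with IAA1, IAA2 and IAA29 at -0.65, -0.21 and -0.74. ERDJ3B, for a co-chaperone of the endoplasmic reticulum, fell among 12 folding genes (-0.40 ± 0.08 SE, adjusted p 0.0394), with CNX1, SHD and ERDJ3A at -0.38, -0.32 and -0.43. Adjusted over the list alone, 3, 2 and 6 members of the 3 lists were lower. The median log2 changes were -0.37, -0.40 and -0.29 in the same order. The auxin call was lost without wild type 1 (0.0623), without pub2pub4 3 (0.0808), under the stricter filter (0.123) and with the replicate number as a block. The 4 gene calls were each lost in at least 4 of the 6 fits with a library left out.

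Of 28 nuclear photosynthesis genes 0 were called by edgeR, with 12 lower at an unadjusted p under 0.05. DESeq2 called 3 lower and limma-voom 0, and 0 were called when adjusted over the list alone. PSAD2 (-0.35, adjusted p 0.0508), LHCB4.2 (-0.39), PSAD1 (-0.20) and PSAF (-0.20) had the smallest p-values. The list's median was -0.17 with a camera adjusted p of 3.33e-04, the adjusted p was 0.564 with an estimated correlation, and fry gave 0.306. Chloroplast-encoded transcripts other than ribosomal RNA took 0.0154% of expected counts in the mutant and 0.0272% in wild type (exact permutation p 0.1).

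The other pathway lists were not called by camera, although single members changed. In the ethylene list of 20 genes ORA59, an activator of defence genes, fell by 1.43 on the log2 scale and EBF2 rose by 0.46, with PR3 and ERS1 at 0.35 and 0.20. In the camalexin and indole glucosinolate list of 17 genes PEN2, a myrosinase of pre-invasion defence, fell by 0.63, and MYB51, IGMT1 and IGMT2 had log2 changes of -0.98, -1.08 and -1.51. In the senescence list of 16 genes SWEET15, a sugar transporter gene at 0.0967 CPM in wild type, rose by 3.76, and SAG113, PPH and NYE1 had changes of 3.18, 0.32 and 0.33. The superoxide dismutase gene FSD1 rose by 0.99 ± 0.11 (SE, adjusted p 0.00743) among 21 oxidative stress genes, while CSD1 and CSD2, for copper-zinc superoxide dismutases, fell by 0.58 and 0.79 and ERF5 had a change of -1.18. In the circadian list of 13 genes LNK2 and PRR7 fell by 0.59 and 0.65 and ELF4 rose by 0.36, with PRR5 at -0.40. Of these called genes only FSD1 was called without each library in turn.

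Adjusted over the list alone, the ethylene list had 1 member higher and 1 lower, camalexin 1 lower, senescence 5 higher, oxidative stress 1 higher and 3 lower, and the clock 1 higher and 2 lower. Their camera adjusted p were 0.898, 0.0600, 0.0658, 0.433 and 0.113 in that order. The camalexin list was called without wild type 3 (0.00291) and without pub2pub4 1 (0.00424), and the senescence list without wild type 2 (0.0487), without pub2pub4 3 (1.17e-05) and without a filter on low counts (0.0387). Both lists were also called with the replicate number as a block. The clock list was called without pub2pub4 3 (0.00546). Fry for either direction gave adjusted p of 0.0176 for the ethylene list, 0.0748 for camalexin, 0.0341 for senescence, 0.0176 for oxidative stress and 0.00529 for the clock.

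Among 9 heat shock genes edgeR called 0, DESeq2 0 and limma-voom 0, with 0 at an unadjusted p under 0.05. HSP17.6II, HSP17.4, HSFA2 and HSP17.6A had log2 changes of -0.46, 0.44, -0.31 and 0.36 (camera adjusted p of the list 0.898). Among 7 phosphate starvation genes the same 3 tools called 0, with 2 higher at an unadjusted p under 0.05. PS2, PAP17, MGD3 and SQD2 had changes of 0.74, 0.97, -0.34 and 0.17. The adjusted p of the phosphate list was 0.139, and 0.0298 without pub2pub4 3. Neither list had a member called when adjusted over the list alone.

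Markers of other cell types were not called as lists. EdgeR called 0 of 6 guard cell and myrosin cell genes, 0 of 7 vasculature genes, 0 of 5 epidermis genes and 0 of 5 dividing cell genes, with 1, 1, 2 and 0 lower at an unadjusted p under 0.05. DESeq2 called 1 guard cell gene lower and 1 epidermis gene higher, and limma-voom called 0 in each list. Adjusted over the list alone, KAT1 (-0.46) and GL2 (-0.42) were lower. Camera adjusted p were 0.818, 0.201, 0.316 and 0.433. The myrosinase genes TGG1 and TGG2 had log2 changes of 0.32 and 0.36, SLAC1 0.23, XCP2 -0.34, XCP1 -0.30, SUC2 -0.11, APL 0.10, ATML1 -0.19, CER1 0.75 and FDH -0.10. The division genes CDKB2;1, CYCB1;2, CDKB1;1 and CYCB1;1 lay between 0.11 and 0.20.

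The floral organ and root lists had too few tested members for a list test after the filter on low counts. Without that filter camera called the 5 floral organ markers lower (adjusted p 0.0116, median log2 change -1.37, all 5 negative, 0 called singly and 1 at an unadjusted p under 0.05), and with an estimated correlation the adjusted p was 0.247. Of the floral genes SEP3 alone was tested (log2 -0.73, adjusted p 0.311), and AG, AP1, AP3 and PI had 29, 25, 11 and 29 counts over the wild-type libraries and 11, 5, 4 and 11 over the mutant ones. Of the root genes CASP1 had 40 counts in wild type and 16 in the mutant, PRP3 5 and 1, COBL9 0 and 3, EXPA7 0 and 1, and MYB36 0 in both.

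The organelle share of the libraries differed in the same direction in every library. Chloroplast-encoded genes took 0.293 ± 0.0884% of expected counts in wild type and 0.0985 ± 0.0215% in pub2pub4 (SD, n = 3 each). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. The wild-type libraries were at 0.255, 0.394 and 0.230% and the mutant ones at 0.0787, 0.0956 and 0.121%. Ribosomal RNA of chloroplasts and mitochondria together took 0.277 ± 0.0842% and 0.0871 ± 0.0213%. Chloroplast genes without ribosomal RNA took 0.0272 ± 0.00660% and 0.0154 ± 0.000482% (exact permutation p 0.1). Mitochondrial genes took 0.0181 ± 0.00506% and 0.0109 ± 0.00126% (exact permutation p 0.1). Of 34 tested mitochondrial genes other than ribosomal RNA edgeR called 0, DESeq2 0 and limma-voom 0, with 4 at an unadjusted p under 0.05 and a median log2 change of 0.07. Of the mitochondrial ribosomal RNA genes RRN18 fell (log2 -0.62, adjusted p 0.0214), and RRN26 was at -1.96 (adjusted p 0.0762). The 10 highest genes took 7.33 ± 0.133% and 7.32 ± 0.595% (exact permutation p 1).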

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

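Every alternative here was planned; no test in this part was chosen after the result was seen. Of the values for named genes under all alternatives, 1593 stayed on their side of the threshold, 249 lost the call and 74 gained one. Some genes that were not called changed direction, as CYCB1;1 did (0.199, and as low as -0.114 with a library left out). None of the 848 calls reversed in sign, and without overlap between the groups a reversal was hardly possible. Leaving out 1 library moved the number of changed genes between 86 (without wild type 2) and 1210 (without pub2pub4 3), higher genes between 42 and 756, lower genes between 44 and 454, those with a log2 change of at least 1 between 23 and 230 higher and 26 and 173 lower, and lists called between 12 and 15; the cause was not tested. In the same fits the adjusted p ran from 2.11e-04 to 0.147 for PTI markers, 4.51e-04 to 0.945 for jasmonate, 0.00291 to 0.589 for camalexin, 1.17e-05 to 0.264 for senescence, 0.0281 to 0.0808 for auxin, 0.00546 to 0.259 for the clock and 0.0298 to 0.505 for phosphate starvation. With the replicate block the count was 1066, of which 489 were higher and 577 lower (45.9% higher, against 55.9%), 225 of the lower genes had a log2 change of at least 1, and the adjusted p was 0.0454 for camalexin, 0.0357 for senescence and 0.0761 for auxin. Deviations from the group mean correlated at 0.126, 0.0642 and 0.152 between libraries of the same number and at -0.176 to 0.0755 between the others. These values leave open whether the numbers mark pairs. Of the 1066 genes called with the block, 688 were among the 848. DESeq2 called 1452 genes, 750 higher and 702 lower, with 209 and 259 of them at a log2 change of at least 1. Without a filter 16 lists were called, with senescence (0.0387) and floral organ markers (0.0116), which the filter leaves too small to test, gained. The stricter filter left 73 higher and 74 lower genes with a log2 change of at least 1, as it tests fewer genes, and gave auxin 0.123. Against 1.5-fold, 26 genes passed, 13 higher and 13 lower, all of them with a log2 change of at least 1 (13 and 13). With an estimated correlation 0 lists were called: the adjusted p was 0.279 for U-box ligases, NLRs, cysteine-rich kinases, aliphatic glucosinolates, endoplasmic reticulum folding, abscisic acid and cold, auxin and anthocyanin, 0.355 for PTI receptors, 0.364 for PTI markers and salicylic acid, 0.429 for type-A regulators and 0.564 for jasmonate and photosynthesis. Fry in one direction called 7 lists and gave 0.105 for PTI receptors, 0.197 for PTI markers, 0.172 for salicylic acid and type-A regulators, 0.0622 for NLRs, 0.354 for jasmonate and 0.306 for photosynthesis. Counts under the other settings were 742 with limma-voom, 859 with median-of-ratios factors, 869 with library totals alone (49.0% higher), 916 without a filter, 740 with the stricter filter, 842 without organelle genes, 856 without the 10 highest genes and 847 without rounding. List tests were not run for DESeq2, limma-voom, no rounding or the test against 1.5-fold. The small prior count that edgeR adds when it computes fold changes was not varied, and it matters most for genes near 0 counts. Depth left 9807 genes without a count.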

Other observations

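The tests on families, gene length and GC content, guard cells, the strongest falls, MAF genes and chloroplast transcripts were chosen after the result was seen. Among families named by product, the A subunits of nuclear factor Y, a transcription factor, had the smallest p among families with risen members: 5 of 10 tested rose (one-sided Fisher adjusted p 0.00147). They are NFYA2 (1.38), NFYA3 (1.13), NFYA5 (1.45), NFYA8 (0.69) and NFYA10 (1.28), called in 6, 3, 3, 1 and 3 of the 6 fits with a library left out. Of 15 purple acid phosphatases 4 rose (adjusted p 0.0480): PAP16, PAP18, PAP22 and PAP27, called in 2, 3, 1 and 0 of those fits. The other families with an excess of risen members were cold regulated proteins (3 of 5) and glucosinolate S-oxygenases (3 of 5, adjusted p 0.0340 for both), zinc-binding dehydrogenases (3 of 6) and beta glucosidases (4 of 15, adjusted p 0.0480 for both). The family of cysteine-rich receptor-like kinases fell in 13 of 29 members (adjusted p 1.88e-12) and S-locus lectin kinases in 4 of 17 (adjusted p 0.0492). Disease resistance proteins fell in 10 of 99 and products whose name begins with receptor in 8 of 63 (adjusted p 0.00718 for both). The last group is a match of names that mixes receptor-like proteins and kinases. CRRSP2, CRRSP38 and CRRSP55, related to the cysteine-rich kinases, are among its fallen members. Another 3 of these 63 products, AtRLP6, AtRLP32 and AtRLP33, rose (1.82, 0.76 and 1.25). These families share members with the lists. The Fisher tests count genes as independent, although members of such lists move together. Estimated correlations were 0.319 in the cysteine-rich receptor-like kinase list and 0.277 in the NLR list. With the estimated correlation, camera gave each of these 2 lists an adjusted p of 0.279. The family p-values therefore do not measure the spread between libraries. Since risen and fallen genes were adjusted apart, families with an adjusted p of 0.0480 or 0.0492 may not pass an adjustment over both directions.

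In all 10 splits of the 6 libraries into 3 and 3, the labelled one gave the most changed genes, 848, and the highest other gave 0, so 1 of 10 splits reached the labelled count. For lists called, 2 of 10 splits reached the labelled 14, and the highest other gave 17. With 10 splits chance cannot be excluded for either count, and the list calls were not more than another split gave.

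Higher abscisic acid and cold genes and lower cysteine-rich kinase genes could come from a bias of gene length or GC content. After a trend on both was subtracted, the medians were 1.41 (bootstrap SE 0.153) and -1.23 (SE 0.215), from 1.48 and -1.25, which argues against it as the whole cause. These SE come from resampling list members as if independent, and they do not measure the spread between libraries. A larger share of guard cells would raise their markers, but the highest of 4, SLAC1, was at 0.23 ± 0.17 (SE), far below 1.48. A response of leaves without PUB2 and PUB4 remains a hypothesis, and a difference in growth or watering between the groups was not tested.

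Outside the targets and the organelles, 12 of the genes called changed had a log2 fold change of -3 or below. They include AT2G01422, a non-coding RNA with 2408 counts in wild type and 3 in the mutant, and PI4KG3. QQS (-3.53), MAF5 (-4.50) and MAF4 (-3.52) are among them too, with QQS still at 1.64 CPM in the mutant. FLC, a relative of MAF4 and MAF5 outside the 2 Mb around PUB2, fell by 2.90 (adjusted p 0.0151). FLC was low, at 0.888 CPM in wild type and 0.114 CPM in the mutant. It was called in 3 of the 6 fits with a library left out. Its whole span of 6067 bases overlaps a gene on the opposite strand, so its reads may be shared. A segment carried along with either mutation could explain genes close to PUB2 or PUB4. Of the 12, 2 (MAF4 and MAF5, which are neighbours) lie within 2 Mb of either gene in TAIR10.1. That is 16.7%, against 6.15% of the tested genes (two-sided Fisher p 0.166), and so few genes cannot decide that comparison. The positions of the other genes argue against such a segment for most of the 12. For MAF4 and MAF5 it cannot be told apart from an effect of the genotype: 17 of 493 other tested genes near PUB2 changed (one-sided Fisher p 0.887), and a variant in the MAF genes alone would leave the neighbours unchanged. Reads passing to paralogs would raise MAF1, MAF2 or MAF3, and the highest of them was at -0.0513 ± 0.12 (SE), which argues against that.

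Of 43 tested chloroplast genes other than ribosomal RNA, 6 fell and 0 rose, with a median log2 change of -0.60, the largest in PSAA (-2.23), PSAB (-2.08) and RPS14 (-2.02), besides PSBD, PSBC and RBCL. Less carried-over organelle RNA in the mutant libraries could lower all of them alike. The fold changes of 11 such genes differed by more than their standard errors (heterogeneity p 8.73e-15), which argues against 1 common loss as the whole cause. Mitochondrial ribosomal RNA was lower too (RRN18 -0.62, RRN26 -1.96), while the other mitochondrial genes had a median log2 change of 0.07. A loss that differs between transcripts, as from selection of polyadenylated RNA, was not tested and stays open beside an effect of the genotype.

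Higher FSD1 with lower CSD1 and CSD2 could be a low-copper response. Among 12 other copper-responsive genes written down before their values were seen, 9 were tested and 5 moved as such a response predicts (signed fry p 0.401). YSL2 (1.09) and CCS (-0.82) changed with it and COPT1 (-0.41) against it. The test cannot tell.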
